A study of Mus musculus with 2 samples.

How the data were processed

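Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in hearts of mouse embryos at 14.5 days of gestation. Per the labels, hearts of several embryos of both sexes were pooled, the mice were healthy animals of a mixed B6NTac and B6NCrl background, and DNA was fragmented by Nextera tagmentation with a size range of 200 to 750, given without a unit. The series holds 1 group with 2 biological replicates, each with 1 library. No second stage, tissue or treatment is part of the series, so the only comparison between samples is replicate 1 against replicate 2, and every other comparison is made within a list of accessible regions.

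The deposited files are lists of peaks in mm10 coordinates. Each replicate has 3 lists made from its own alignment, per the deposited notes: peaks ranked by the irreproducible discovery rate (IDR), peaks that pass an IDR threshold, and a longer list of pseudoreplicated peaks. Further lists were made from the alignments of both replicates: a conservative IDR thresholded list, a second IDR thresholded list, replicated peaks, pseudoreplicated peaks and 2 IDR rankings, which makes 12 lists in all. The notes name 1 more interval file, not used here, as an input of every list except the rankings. The aligner, the peak caller, their versions and any shift of read ends for the transposase are not given in the sources used here.

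Each deposited row gives an interval, a summit, a signal value and a p-value. The signal value of a peak is the authors' own number, never negative, and what it is relative to is not given in the sources used here. It serves only to describe and rank peaks inside the list it stands in. The authors deposited p and q of each peak as −log10 values, and the lowest −log10 p was 2.00 in each of the 12 lists. In the rankings the authors deposited the global IDR of each peak as a −log10 value too, and every peak of the conservative list passed an IDR of 0.05 in the ranking it was matched to. The summit is deposited as an offset in bp from the start of the interval. Read counts and library sizes are not part of these files, so the depth is unknown, and intervals given below cover counting error over regions only.

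Overlapping rows, several summits of 1 interval among them, were merged into regions when they shared at least 1 bp. A region took the summit and the signal value of its strongest row. The main list was the conservative one, and the IDR thresholded list of each replicate stands beside it. Regions on the 21 assembled chromosomes (2726 Mb) were used. Every interval on these chromosomes lay inside the sequence of the GRCm38 reference, the same build as mm10. Genes were the 21827 protein-coding genes of the GENCODE M21 basic set, with 41406 transcription start sites (TSSs).

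Replicates were compared as the share of 1 replicate's regions that touch a region of the other by at least 1 bp, with an exact (Clopper-Pearson) 95% interval and beside 100 circular shifts of the other list within chromosomes. Regions were assigned by their summit to promoter (a TSS within 1000 bp), UTR, coding exon, intron or intergenic sequence, in that order. A gene had a promoter region when any part of a region lay within 1000 bp of 1 of its TSSs. Distal regions lay over 1000 bp from every TSS of protein-coding genes and were counted within 50000 bp of a gene's TSSs. Starts of genes that do not code for protein were not used, so distal and intergenic regions can include them. A region can count for more than 1 gene.

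Gene lists were written before the data were examined: 19 lists of known marker genes with 339 genes in all, plus the Hox genes and the olfactory receptors, 21 lists together. The gene Ahsp was not found in the annotation. Each list was set against 10000 random lists of as many protein-coding genes and is said to stand apart outside the middle 95% of these. A value equal to an edge of this range counts as inside, even where ties put the percentile below 2.5 or above 97.5. The percentile describes these libraries and is no p-value, since genes are not replicates. Random lists draw scattered genes, whereas Hox genes and olfactory receptors lie in clusters, so the random range can be too narrow for these lists. Other lists hold some neighbours too, such as Myh6 and Myh7 or Nppa and Nppb, which can count the same distal region. Matches to 25 consensus motifs on either strand were counted in 201 bp around each summit, and in 201 bp windows centred 1500 bp to each side that touch no peak. Ratios of shares carry 95% intervals (log method) from counts. Regions separated by at most 12500 bp were joined into clusters, ranked by the sum of the authors' signal values of their peaks.

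The genes named were chosen by a rule written beforehand. For each list it takes the 2 members with the highest signal value at a promoter region and up to 2 members without a promoter region, in list order. Nkx2-5, Gata4, Tbx5, Hand2, Mef2c, Tnnt2, Myh6, Myh7, Actc1, Nppa, Nppb and Myl7 are always named. The rule also takes the nearest genes of the 10 strongest distal regions and of the 10 highest clusters, and the 10 genes with most distal regions.

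Alternatives fixed beforehand were other peak lists, each replicate alone, the upper 50% of regions by signal value, other overlap rules, promoter windows of 500 and 2000 bp, distal windows of 20000 and 100000 bp, random lists matched on promoter CpG content or gene length, a dinucleotide-shuffled background, a motif window of 101 bp and a joining gap of 5000 bp. Added after the data were examined were the removal of regions that align to the mitochondrial genome (BLAST+ 2.17.0, E-value at most 1e-10, at least 50% of the region's length) and the removal of promoter regions shared with another gene. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0, and samtools 1.23.1 for the sequence index.

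The statistics were tested on simulated data. With 70.4% of 11908 regions planted as shared, 70.4% were found. Of simulated lists with no difference among 21827 genes, 4.70% stood apart, and of lists planted at a share of 90%, 99% stood higher. A motif ratio planted at 3.03 in 6000 windows was found at 3.03, and 1.01 was found without planting. In these simulations the shared regions were shifted copies, genes were independent and sequences were random with equal base shares. They therefore check the computation only, and not the choice of background or of random lists.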

Results

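Accessible chromatin of the embryonic mouse heart at day 14.5 was profiled by ATAC-seq in 2 biological replicates of pooled hearts. The conservative list, made by the authors from both replicates, held 35968 peaks, which merged into 17129 regions that cover 13.4 Mb or 0.490% of the assembled chromosomes. The regions had a median width of 756 bp and a median signal value of 7.43 (interquartile range 5.62 to 10.4). The IDR thresholded list of replicate 1 gave 11908 regions over 8.59 Mb, and that of replicate 2 gave 12713 regions over 9.82 Mb. Sequencing depth is unknown, because the lists carry no read counts.

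Accessible regions lay mainly at gene starts. In the conservative list 59.7% of regions (10219 of 17129, exact 95% interval 58.9 to 60.4%) had their summit within 1000 bp of a TSS, 30.2 times the 1.97% of sequence that such windows take. Introns held 18.0% of regions against 33.2% of the sequence, and intergenic sequence held 20.7% against 62.5%. UTRs held 0.946% and coding exons 0.701% of regions. Promoter regions had higher signal values and were wider than the others: their median signal value was 9.12, against 5.82 in introns and 6.29 between genes, and their median width was 897 bp, against 522 and 577.5 bp. The promoter share was 70.7% in replicate 1 and 70.6% in replicate 2, and it was 32.7% in the longer list of replicated peaks. Of all 21827 protein-coding genes, 49.3% had a promoter region in the conservative list, 41.2% in replicate 1 and 44.2% in replicate 2.

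Promoters of cardiac transcription factor and sarcomere genes were accessible more often than those of random genes in the conservative list. Among cardiac transcription factors 17 of 21 genes (81.0%) had a promoter region, against 28.6 to 71.4% in the middle 95% of random lists. Hey2, a ventricular Notch effector, had the highest signal value of this list, 13.9 (12.2 in replicate 1 and 14.4 in replicate 2), at chromosome 10, 30842316 to 30843484. Tbx20 followed with 11.8 at chromosome 9, 24774060 to 24774828. Nkx2-5, the homeodomain factor of the cardiac lineage, had a region with a value of 9.23 at chromosome 17, 26841325 to 26841770 (8.68 and 8.12 in the replicates). Gata4 had 6.94 at chromosome 14, 63245134 to 63245741, and Mef2c had 5.96 at chromosome 13, 83524135 to 83524935, beside an internal start site. Hand2 had 5.85 at chromosome 8, 57320750 to 57321175, and was listed in replicate 2 only (6.86). Tbx5 and Tbx2 had no promoter region here, but both had one among the replicated peaks, with values of 3.17 and 3.05. The list fell inside the range of random lists matched on promoter CpG content (percentile 73.2) and in the upper 50% of regions by signal value (10 of 21 genes, percentile 88.2).

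Genes of the sarcomere, the contractile unit of muscle, showed the same with 21 of 24 (87.5%) promoters accessible, against 29.2 to 66.7% of random lists (percentile 100). The atrial light chain Myl4 had the highest value, 10.7 at chromosome 11, 104549999 to 104550909, in a region that also lies within 1000 bp of a TSS of Cdc27. Tnni1, the slow skeletal troponin I of the fetal heart, had 10.1 at chromosome 1, 135800031 to 135800964, and Tnnt2, cardiac troponin T, had 8.92 at chromosome 1, 135835866 to 135836669. Actc1, cardiac actin, had 7.12 at chromosome 2, 114052662 to 114053404. The myosin heavy chains had lower values, 4.54 for Myh7 at chromosome 14, 54994351 to 54995152, and 3.82 for Myh6 at chromosome 14, 54966528 to 54967116. Myl7 had 4.40 at chromosome 11, 5898613 to 5898983, and was in neither replicate's own list. Myom2 and Obscn had no promoter region in the conservative or the replicated list. In the upper 50% of regions by signal value 6 of 24 sarcomere genes were left (25%, percentile 15.6).

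In fatty acid and energy metabolism 23 of 25 genes (92.0%) had a promoter region, led by Cpt2 of mitochondrial fatty acid import with 12.5 (chromosome 4, 107923236 to 107923802) and Pdk4, an inhibitor of pyruvate oxidation, with 12 (chromosome 6, 5495979 to 5496890). Cd36 and Mb were without one in the conservative list and had values of 4.33 and 3.10 among the replicated peaks. In conduction, calcium handling and natriuretic peptides 14 of 20 genes (70.0%) had one, at the upper edge of random lists (25 to 70%) and not outside it. The potassium channel gene Kcnj2 had 15.3 at chromosome 11, 111065580 to 111066514, and Cacna1c, the L-type calcium channel, had 10.3 at chromosome 6, 119196408 to 119196895. Of the natriuretic peptide genes, Nppb had 10.1 at chromosome 4, 147985342 to 147986061, and its neighbour Nppa had 4.51 at chromosome 4, 148000123 to 148000754, with no region in either replicate's own list. Scn5a and Hcn4 had no promoter region in the conservative list and values of 3.44 and 3.56 among the replicated peaks. Replicate 1 alone gave 7 of 20 genes in this list and replicate 2 gave 11 of 20, both inside the random range, as were the 7 of 20 in the upper 50% of regions by signal value. The list stood higher in the second IDR thresholded list (16 of 20, percentile 99.8), among the replicated peaks (20 of 20, percentile 100) and with promoter regions shared with another gene left out (13 of 20, percentile 98.8). Cell cycle genes were accessible in 16 of 18 cases (88.9%), with 18.1 at Ccna2 and 15.7 at Pcna, while Ccnd1 and Bub1 had no region in the conservative list. Bub1 had one in replicate 2's own list (9.24) and among the replicated peaks (6.285), and Ccnd1 had one among the replicated peaks only (3.06). Housekeeping genes were accessible in 23 of 24 cases, led by Tfrc with 14.4 and Sdha with 14.2. The region of Sdha is shared with Ccdc127, and Psmb4 was the gene without a region in the conservative list (4.20 among the replicated peaks). Against lists matched on CpG content the metabolism, sarcomere and housekeeping lists still stood higher, and the cell cycle list did not (percentile 84.8).

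**Figure D1:**
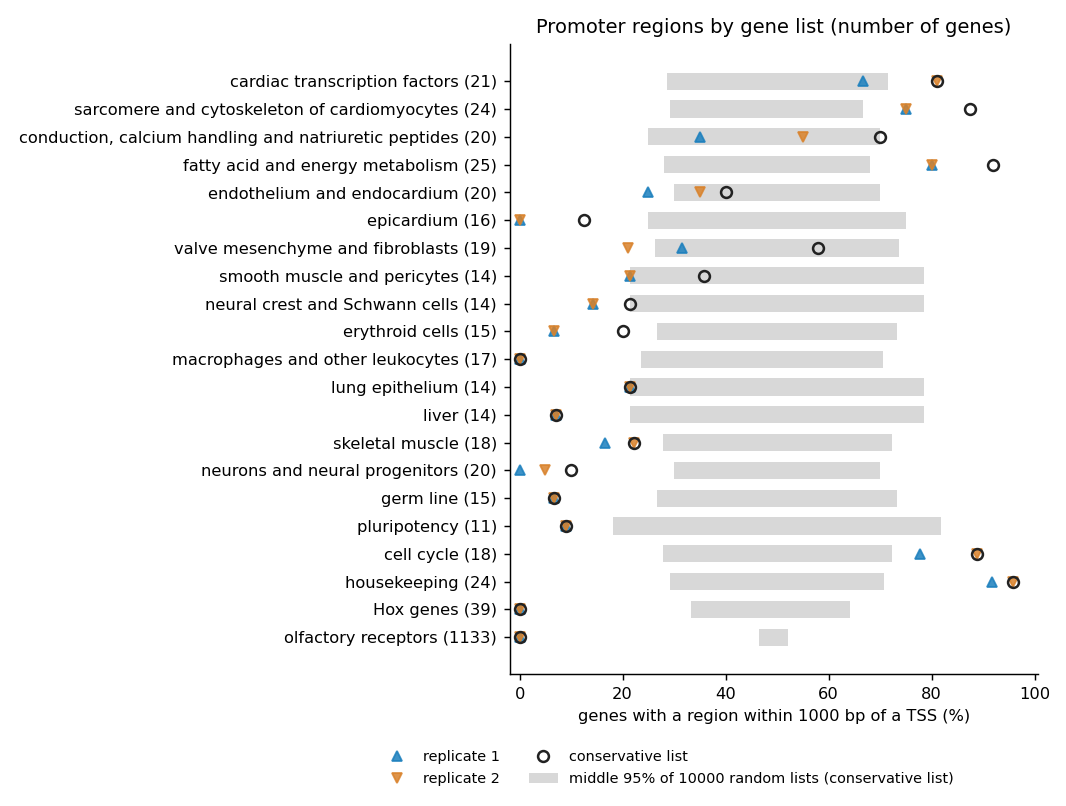
Percent of genes with a region within 1000 bp of a TSS (horizontal axis) for each gene list, with the number of genes in brackets; circles are the conservative list, triangles the replicates' own lists, and grey bars the middle 95% of 10000 random lists scored in the conservative list, so the bars do not apply to the triangles. The circles of the cardiac transcription factors (81.0%), sarcomere (87.5%), fatty acid and energy metabolism (92.0%), cell cycle (88.9%) and housekeeping genes (95.8%) lie to the right of the bars, while Hox genes and leukocyte genes lie at 0.

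Genes of the other cell types of the heart were accessible at the rate of random genes or below it in the conservative list. Among the replicated peaks, where the share over all genes rose from 49.3% to 60.7%, only the endothelial and the valve lists of these stood higher. Endothelial and endocardial genes had a promoter region in 8 of 20 cases (40.0%, percentile 20.9), in 5 of 20 in replicate 1 (25%, percentile 7.25) and in 7 of 20 in replicate 2 (percentile 20.6). Tie1 had 9.43 at chromosome 4, 118489560 to 118490202, and Kdr, the VEGF receptor, had 7.23 at chromosome 5, 75978024 to 75978923, while Pecam1 and Cdh5 had none in the conservative list. Cdh5 had one in replicate 2's own list (5.57) and among the replicated peaks (5.48). Among the replicated peaks 18 of these 20 genes (90%) had a promoter region and the list stood higher than random lists, whereas in the upper 50% of regions by signal value it stood lower (1 of 20). Valve mesenchyme and fibroblast genes had 11 of 19 (57.9%, percentile 76.2) in the conservative list and 17 of 19 (89.5%, higher) among the replicated peaks. They had 6 of 19 (31.6%, percentile 20.5) in replicate 1 and 4 of 19 in the upper 50%, both inside the range. In replicate 2 they had 4 of 19 (21.1%, percentile 2.05), inside the range but exactly at its lower edge. In the conservative list Snai1 had 11.1 at chromosome 2, 167537858 to 167538531, and Snai2 had 10.2 at chromosome 16, 14705240 to 14705999, both drivers of the change from endothelium to mesenchyme, while Postn (4.33 among the replicated peaks) and Col3a1 had no region. Smooth muscle and pericyte genes were accessible in 5 of 14 cases (35.7%), with Smtn at 7.20 and Synpo2 at 6.52, and Acta2 and Tagln had a region among the replicated peaks only (4.83 and 4.37). The smooth muscle list had 3 of 14 in each replicate and 11 of 14 among the replicated peaks, inside the range in each, and stood lower in the upper 50% (0 of 14). Epicardial genes stood lower, with 2 of 16 (12.5%, random lists 25 to 75%). These were Tbx18 with 5.36 and Krt8 with 4.80, neither of them in a replicate's own list, where 0 of 16 genes had a region. Wt1 and Tcf21, transcription factors of the epicardium, reached 3.64 and 3.91 among the replicated peaks only. With 7 of 16 (43.8%) among the replicated peaks, the epicardial list was inside the random range there (percentile 9.48).

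Blood cell genes and genes of other tissues were accessible less often than random genes in the conservative list, though several of these calls depended on the list or the matching. None of 17 leukocyte genes had a promoter region in the conservative list, the replicated peaks or either replicate, Ptprc and Spi1 included. Erythroid genes had 3 of 15, among them the erythroid factor Klf1 with 5.83 and the erythropoietin receptor gene Epor with 4.55, while the globin genes Hba-a1 and Hbb-bs had none. Skeletal muscle genes had 4 of 18. The highest were Actn3 with 11.8 and Mylpf with 9.28, whose regions lie within 1000 bp of a TSS of Zdhhc24 and of Tbc1d10b as well, and the muscle determination genes Myod1 and Myf5 had none. The only liver gene of 14 was Foxa3 with 9.25, in a region shared with Sympk, while Alb and Afp had none. Neuronal genes had 2 of 20, Elavl4 with 7.65 and Sox2 with 6.05, and Rbfox3 and Neurod1 had none. Germ line genes had 1 of 15, Dazl with 11.6, and not Ddx4 or Sycp1. Pluripotency genes had 1 of 11, Esrrb with 5.99, and neither Pou5f1 nor Nanog. Hox genes had 0 of 39, Hoxb13 and Hoxb9 first in order among them, and olfactory receptors had 1 of 1133, Olfr607 with 8.24. All these lists stood lower than random lists in the conservative list. Erythroid genes had 1 of 15 in each replicate's own list, and neuronal genes had 0 of 20 in replicate 1 and 1 of 20 in replicate 2, all lower as well. Among the replicated peaks erythroid genes had 8 of 15 (53.3%, percentile 28.0) and neuronal genes 8 of 20 (40%, percentile 3.33), and both calls ended. With promoter regions shared with another gene left out the erythroid (percentile 6.76) and pluripotency (1.78) calls ended. With a promoter window of 2000 bp the liver call ended (3 of 14, percentile 1.72). The pluripotency and liver shares then equalled the lower edge of the range, so these calls ended on a tie. The regions of Epor and Sox2 were in neither replicate's own list. Neural crest and Schwann cell genes (3 of 14) lay at the lower edge of the random range. Mitf had 13.2 (7.79 in replicate 1 and 15.2 in replicate 2) and Mpz 11.1 in a region shared with Sdhc, while Sox10 and Plp1 had none. Lung epithelium genes (3 of 14) lay at the same edge, with Etv5 at 13 and Abca3 at 10.2 in a region shared with Abca17. Nkx2-1 and Sftpc had none. Both lists stood lower among the replicated peaks (4 of 14 each, percentiles 0.890 and 0.975). The neural crest list stood lower also in the second IDR thresholded list (2 of 14, percentile 0.415) and in replicate 2 (2 of 14, percentile 1.06). Matching on CpG content gave both a lower call as well (percentile 0.0400 for neural crest and 1.23 for lung) and put the leukocyte (percentile 3.17), liver (8.69), skeletal muscle (7.36) and erythroid (55.4) lists inside the range. The matched range of the leukocyte list began at 0, so no lower call was possible for it. The liver share (7.14%) equalled the lower edge of its matched range, while the erythroid share (20%) equalled the matched median. The skeletal muscle list was also inside the random range in each replicate's own list (percentiles 1.75 and 3.23), but exactly at its lower edge.

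Distal regions were more frequent around heart muscle and endothelial genes than around random genes. A protein-coding gene had on average 0.447 distal regions within 50000 bp of its TSSs (0.232 in replicate 1 and 0.255 in replicate 2), and 28.8% of genes had at least 1 in the conservative list. Cardiac transcription factors had 1.90 on average (random lists 0.143 to 0.857; 1.05 in replicate 1 and 1.10 in replicate 2). Conduction and calcium handling genes had 1.65 (1.05 and 1 in the replicates), sarcomere genes 1.54 (1.08 and 0.792), endothelial and endocardial genes 1.2 (0.55 and 1), and fatty acid and energy metabolism genes 1.12 (0.56 and 0.84). These 5 lists stood higher than random lists, in each replicate's own list too. The calls of the endothelial and the metabolism lists ended when only the upper 50% of regions by signal value was used (means of 0.1 and 0.2). Cell cycle genes had 0.667, inside the random range. Housekeeping genes had 0.667 as well, inside the range in the conservative list (percentile 88.4) but above it in the second IDR thresholded list (0.917, percentile 98.6), among the replicated peaks (3, percentile 99.0), in replicate 1 alone (0.542, percentile 98.7) and within 100000 bp (1.54, percentile 98.1). Valve mesenchyme and fibroblast genes had 0.842, smooth muscle and pericyte genes 0.714, neural crest and Schwann cell genes 0.857, skeletal muscle genes 0.833 and erythroid genes 0.600, also inside it. Also inside the range were epicardial genes with 0.375, lung epithelium genes with 0.429, liver genes with 0.357, neuronal genes with 0.400, germ line genes with 0.533, pluripotency genes with 0.273 and leukocyte genes with 0.235. Within 20000 bp the valve list stood higher (0.526, percentile 99.2). Within 50000 bp in the replicates, with their lower mean over all genes, the valve (0.316 in each), smooth muscle (0.214 in each) and skeletal muscle lists (0.222 and 0.278) were inside the range. Olfactory receptors stood lower with 0.0450. Hox genes had 0.231, at percentile 4.21, and 0 in either replicate's own list, where the list stood lower. It also stood lower in the second IDR thresholded list, among the replicated peaks, in the upper 50% of regions by signal value and within 100000 bp. Neighbouring Hox genes can share a region, which random lists of scattered genes do not reflect. The same holds for Myh6 and Myh7 in the sarcomere list and for Nppa and Nppb in the conduction list.

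**Figure D2:**
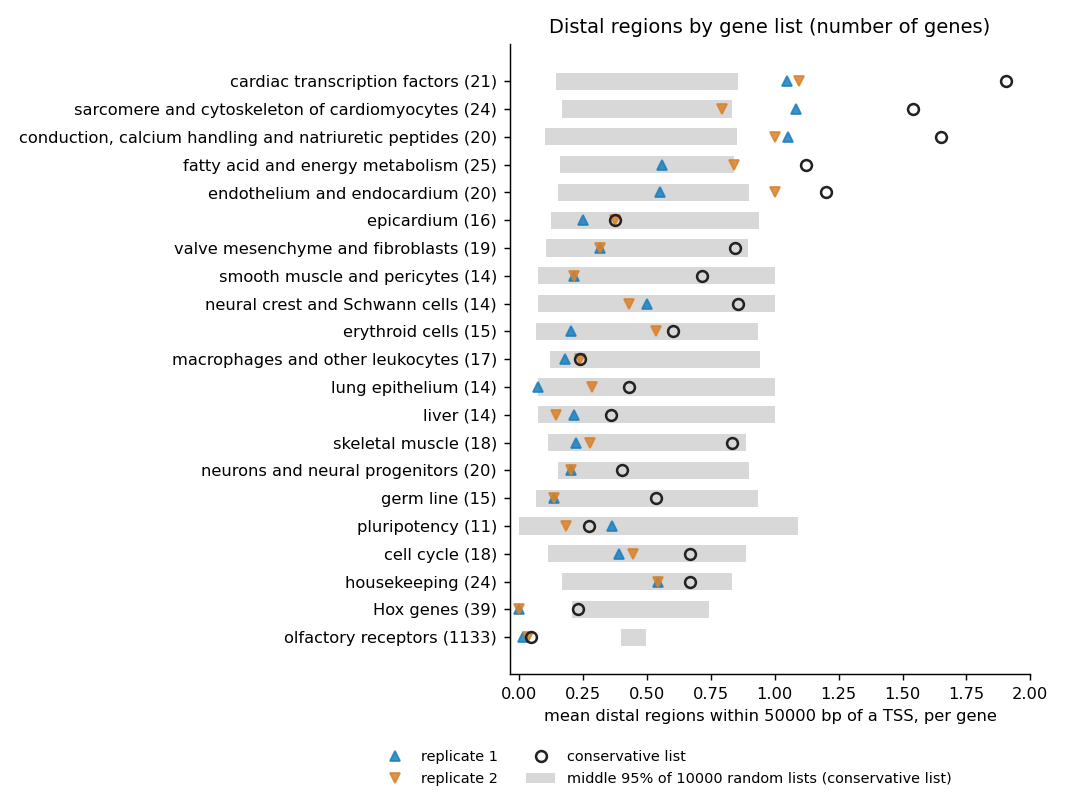
Mean number of distal regions within 50000 bp of a gene's TSSs (horizontal axis, regions per gene) for each gene list, with the number of genes in brackets; circles are the conservative list, triangles the replicates' own lists, and grey bars the middle 95% of 10000 random lists scored in the conservative list, so the bars do not apply to the triangles. The circles of the cardiac transcription factors (1.90), conduction (1.65), sarcomere (1.54), endothelium (1.2) and fatty acid and energy metabolism (1.12) lie to the right of the bars.

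Single loci showed where these distal regions lay. Mef2c had 5, all in its introns, and the strongest of them, with a signal value of 9.63 at chromosome 13, 83565682 to 83566114, held a GATA match (AGATAA) and a TEAD match (AGGAATGC on the forward strand). Another intronic region of Mef2c, at chromosome 13, 83603814 to 83604186 with a value of 6.19, held the MEF2 consensus CTAAAAATAG at 83603975 to 83603984 and again at 83603997 to 83604006, and was in neither replicate's own list. Nkx2-5 had 4, of which the strongest, with 8.30, lay in intergenic sequence 27126 bp upstream at chromosome 17, 26868691 to 26869184, and was listed in replicate 1 only. Gata4 had 4, from 2457 bp upstream of its TSSs (chromosome 14, 63247728 to 63248139, value 5.15) to an intron of the gene Fdft1 48435 bp away. Hand2 had 3, all in intergenic sequence downstream of its start, the farthest with 7.45 at chromosome 8, 57353396 to 57354252. Tbx5, without a promoter region, had 1 in its intron at chromosome 5, 119845051 to 119845500, with 5.35. Tnnt2 had 2, and Nppa and Nppb shared 1 at chromosome 4, 147969185 to 147969753, with 4.40. Actc1 and Myl7 had none.

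The Myh6 and Myh7 genes, which encode the α and β myosin heavy chains, lie in tandem on chromosome 14 and shared 3 distal regions. The strongest lay in intergenic sequence 9149 bp upstream of Myh7 at 55003775 to 55004913, with a signal value of 7.45 (7.33 in replicate 1 and 6.54 in replicate 2), above the 4.54 of the Myh7 promoter region in the same list. It held the MEF2 consensus CTAATAATAG at 55004113 to 55004122, in the sequence TGCTAGGTTCCTAATAATAGCCATGGCTGG (55004103 to 55004132). The region 2103 bp upstream of Myh7, at 54996729 to 54997207 with 5.56, held a CArG box, the binding sequence of serum response factor, CCAAATAAGG at 54997021 to 54997030. The third, at 54988471 to 54989186 with 3.86, lay in an intron of Myh7 and was in neither replicate's own list. Replicate 1 had a further region between the genes, at 54968002 to 54969063 with 4.71, that the conservative list does not hold.

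**Figure D3:**
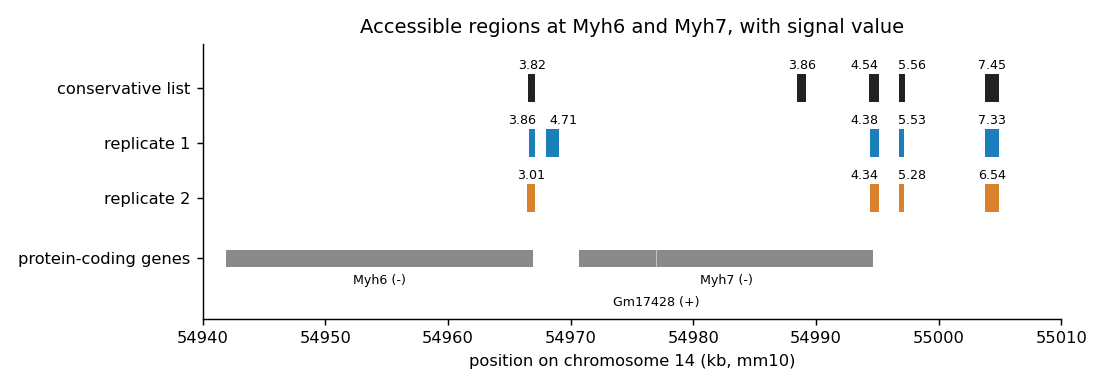
Map of chromosome 14 (horizontal axis in kb, mm10) around Myh6 and Myh7, with protein-coding genes as grey bars (strand in brackets) and accessible regions to scale in the conservative list and in each replicate's own list. The number over a region is the authors' signal value, highest at the region upstream of Myh7 in the 3 lists (7.45, 7.33 and 6.54).

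Genes with most distal regions within 50000 bp were Dab2ip, Kcnq1, Lyl1, Mical2 and Tgm2, with 8 each. Kcnq1 encodes a cardiac potassium channel, Lyl1 a blood and endothelial transcription factor, and Mical2 an actin oxidase. Kcnq1 had 5 such regions in replicate 1 and 3 in replicate 2, and Mical2 had 4 in each. Dab2ip had 2 in each, Lyl1 had 4 and 5, and Tgm2 had 5 and 2. Abt1, BC107364, Btn1a1, Chd3 and Cyb5d1 came next with 7 each, first in alphabetical order among 21 genes with that number. Neighbouring genes can count the same regions here. Abt1 and Btn1a1 lay at 1 cluster of regions, and Lyl1 lay at 1 with Nacc1 and Trmt1.

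At 6747 distal regions the consensus of MEF2 factors, which activate muscle genes, matched in 3.02% of summit windows against 0.271% of flanking windows, a ratio of 11.2 (95% interval 7.82 to 16.0). At 10382 regions with any part within a promoter window the same consensus matched in 0.356% against 0.400%, a ratio of 0.891 (0.604 to 1.31). The TEAD consensus had a distal ratio of 2.51 (2.22 to 2.84), the muscle E-box 2.27 (2.12 to 2.43), AP-1 2.21, MEIS 2.16 (1.99 to 2.35), the CArG box 1.70 (1.32 to 2.19) and GATA 1.35 (1.25 to 1.46). Distal ratios of the insulator factor CTCF and of SP/KLF factors were 10.5 (6.83 to 16.3) and 8.06 (6.31 to 10.3). Distal ETS (3.77), NRF1 (5.75), NFY (1.49) and PU.1 (1.65) ratios were also above 1. Starts of genes that do not code for protein can be among the distal regions. The NKX2 consensus had a distal ratio of 0.986 (0.903 to 1.08), and TBX had 0.552 (0.392 to 0.776). Intervals of SOX, ESRR, POU and HNF4 included 1 at distal regions, FOX (0.577), RUNX (0.771) and the HAND E-box (0.917) were below it, and YY1, HNF1 and REST gave no ratio because a count was 0. At promoter regions SP/KLF matched in 23.4% (ratio 29.2, 25 to 34.2), NFY in 23.8% (4.19, 3.92 to 4.47), ETS in 7.30% (37.4, 27.2 to 51.6), NRF1 in 1.86% and YY1 in 1.55% of windows. Promoter ratios of CTCF (5.48), PU.1 (1.45), MEIS (1.21) and the muscle E-box (1.22) were also above 1.

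The background decided several of these ratios. Against dinucleotide-shuffled sequences of the same windows the distal ratios were 51.0 for MEF2 (19.0 to 137), 3.41 for GATA, 2.96 for TEAD, 2.87 for the CArG box and 1.22 for the muscle E-box. The promoter ratio of MEF2, near 1 against the flanks, was 18.5 (4.46 to 76.7), and those of ETS and SP/KLF fell to 15.2 and 7.10. At promoters, ratios under 1 against the flanks turned above 1 for GATA (0.181 to 1.12), TEAD (0.561 to 1.35), CArG box (0.742 to 2.69), AP-1 (0.559 to 1.5), ESRR (0.190 to 3), SOX (0.5 to 1.12), FOX (0.279 to 2.76) and RUNX (0.230 to 1.41), and the muscle E-box fell to 0.980. The intervals of GATA, SOX, RUNX and the muscle E-box at promoters included 1 there. The distal ratios of FOX and RUNX turned to 2.76 and 1.55, those of ESRR (2.29), POU (2.29) and SOX (1.27) came to lie above 1, and the HAND E-box call ended (0.990). Among the replicated peaks the distal ratios of MEF2 and SP/KLF were 6.98 and 4.16 and the TBX call ended (0.868), and in the upper 50% of regions by signal value MEF2 had 6.78 and ETS 17.6. The distal ratio of CTCF was 6.01 in replicate 1 and 6.43 in replicate 2, and that of ETS was 7.35 in replicate 2.

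**Figure D4:**
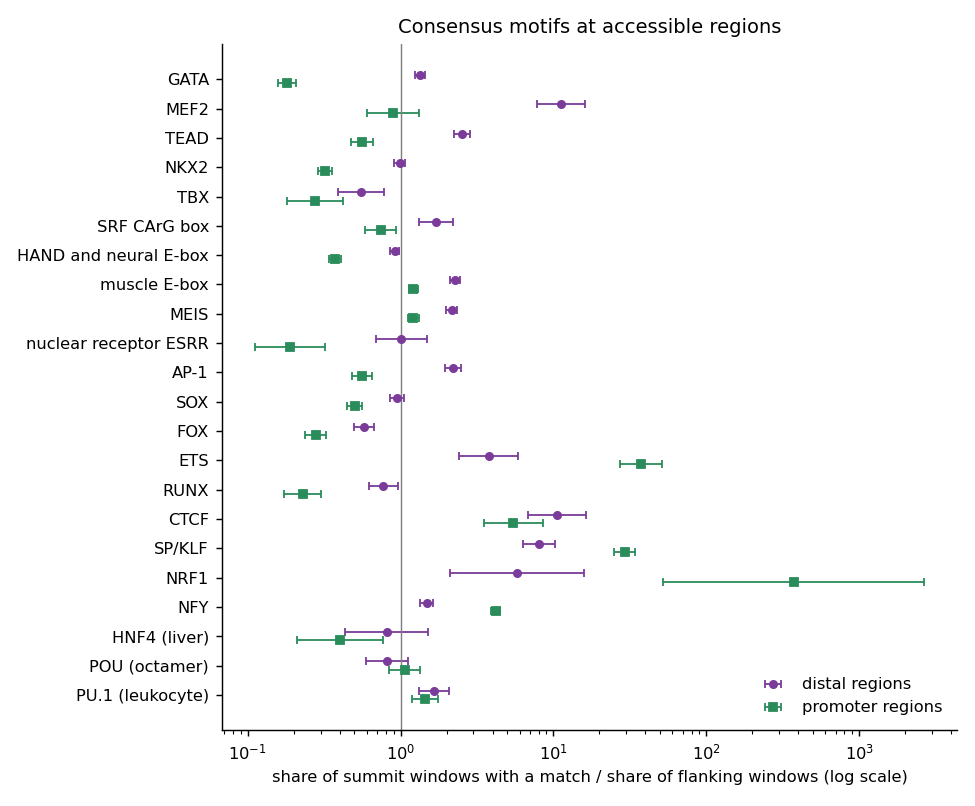
Ratio of the share of summit windows with a consensus match to that of flanking windows (horizontal axis, log scale, no unit) for distal and promoter regions of the conservative list; bars are 95% intervals from counts and the vertical line marks 1. TEAD (2.51 distal, 0.561 promoter) lies on opposite sides for the 2 classes, MEF2 lies above 1 at distal regions (11.2) while its promoter interval includes 1, and ETS (37.4) and SP/KLF (29.2) are highest at promoters; motifs with a count of 0 are not drawn.

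Joined across short gaps, the regions formed 13656 clusters, 2476 of them with several regions. The highest summed signal value, 114, belonged to a histone gene cluster on chromosome 13, 23517557 to 23586179, with 14 regions at Hist1 genes (Hist1h1d, Hist1h2ad, Hist1h2ae, Hist1h2bh, Hist1h3e and others). Next came clusters at Eapp (chromosome 12, 96.9), at Rassf1, Tusc2 and the hyaluronidase genes Hyal1 and Hyal2 (chromosome 9, 92.6), at Shc1, Pygo2 and Flad1 (chromosome 3, 90.3), at Mid1 and Gm21887 (X chromosome, 84.3), and at Ercc1, Fosb and Rtn2 (chromosome 7, 77.3). The places after these went to Hic2 and Ube2l3 (chromosome 16, 77.0), Abt1 and Btn1a1 (chromosome 13, 76.7), Bcl2l2 and Pabpn1 (chromosome 14, 76.3), and Dctpp1 and Sephs2 (chromosome 7, 74.8). None of the 10 was still among the highest with a joining gap of 5000 bp, and replicate 1 and replicate 2 alone kept 3 and 4 of them. This histone gene cluster was not among the 10 highest in replicate 2 alone or in the upper 50% of regions by signal value, and was highest in replicate 1 alone (84.2). In replicate 2 alone another cluster of Hist1 genes, on chromosome 13 at 23738655 to 23762579, took place 7 (67.3).

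The 10 distal regions with the highest signal value all lay between protein-coding genes and were listed in both replicates. The nearest genes were Abcb11 (57.7, chromosome 2, 69355470 to 69355735), Pak3 (54.7), Gm5426 (47.5), G6pd2 (45.5), Frmd4a (36.2), Hic2 (31.8), Tyrp1 (31.4), Myl12b (31.0), Galc (29.7) and Nxph1 (28.4). Those nearest to Gm5426, G6pd2, Tyrp1, Galc and Nxph1 align to the mitochondrial genome over at least 50% of their length, and that of Abcb11 over 48.5%.

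The replicates shared most of their accessible regions. Of replicate 1's regions 84.6% (10071 of 11908, exact 95% interval 83.9 to 85.2%) touched a region of replicate 2, against a mean of 0.757% and at most 0.991% in 100 circular shifts. Of replicate 2's regions 78.6% (9987 of 12713, 77.8 to 79.3%) touched one of replicate 1, against a mean of 0.698%. Promoter regions were shared more often than distal regions, 92.7% against 64.3% in replicate 1 and 86.0% against 60.1% in replicate 2. The share rose with signal value, from 54.2% in the lowest decile of replicate 1 to 100% in the highest, and from 47.2% to 99.2% in replicate 2. Regions assigned to promoters by summit had higher median signal values than those in introns and intergenic sequence. The medians were 9.19, 6.58 and 7.02 in replicate 1, and 9.375, 6.61 and 7.08 in replicate 2. The parts of class and of signal value in the sharing were not separated. When the longer pseudoreplicated list of the other replicate was used, 98.7% of replicate 1's and 97.6% of replicate 2's regions were found there. The gap between promoter and distal regions was then small, 99.6% against 96.6% in replicate 1 and 98.9% against 94.5% in replicate 2. In the conservative list 57.7% of regions were in the lists of both replicates, 7.81% in that of replicate 1 only, 12% in that of replicate 2 only and 22.5% in neither, and 96.3% were in both pseudoreplicated lists. With 1 library on each side, these shares compare the 2 libraries and carry no test of a difference between hearts.

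**Figure D5:**
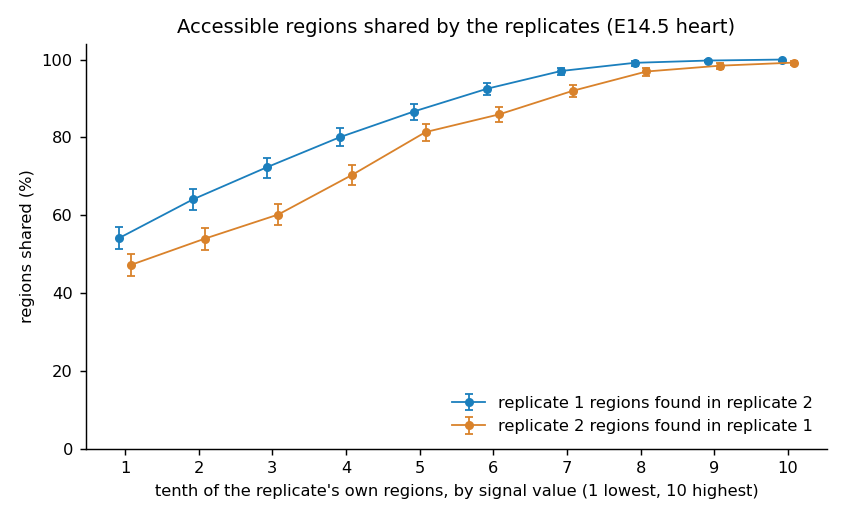
Percent of a replicate's accessible regions that touch a region of the other replicate (vertical axis), by decile of the replicate's own signal value (horizontal axis, 1 lowest and 10 highest); bars are exact 95% intervals. Both lines rise, from 54.2% to 100% for replicate 1 and from 47.2% to 99.2% for replicate 2.

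Regions of 1 replicate only, absent even from the other's pseudoreplicated list, were few. Replicate 1 had 150 of them (1.26%) and replicate 2 had 299 (2.35%). They were less often at promoters than shared regions, 24.0% (17.4 to 31.6%) against 72.0% in replicate 1 and 32.8% (27.5 to 38.4%) against 72.3% in replicate 2. Their median signal value was 5.57 against 8.34 in replicate 1 and 5.92 against 8.54 in replicate 2. No region of replicate 1 alone and 3 regions of replicate 2 alone were nearest to a gene of the lung, liver, skeletal muscle, neuronal, erythroid or leukocyte lists.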

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

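The alignment of regions to the mitochondrial genome was the test chosen only after the strongest regions had been seen.

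A signal appeared in data that the comparisons above do not use. In the IDR ranking made from both replicates, 107 regions passed an IDR of 0.05 and were absent from the conservative list, 67 of them on assembled chromosomes and 40 on scaffolds. The strongest by −log10 p, 8175.5, lay on chromosome 1 at 24611586 to 24616165, and another with a signal value of 41.7 lay on chromosome 6 at 103648979 to 103649356. The 67 are not separate loci, since several lay close together. Examples are chromosome 9 from 2999934 to 3038289 and chromosome 14 from 19415649 to 19418965. Per the deposited notes the ranking was made without the additional interval file that the conservative list used, and that file was not used here. Only the rankings hold peaks on scaffolds. Whether the file accounts for the absent regions was not tested.

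Reads of the mitochondrial genome placed on nuclear copies of it were weighed for the strongest regions. Of the absent regions on chromosomes, 9.55% of the bases aligned to the mitochondrial genome, all in the chromosome 1 region, so 66 of 67 are not accounted for. This explanation is excluded as the whole cause for the absent regions on chromosomes. Those on scaffolds were not part of this test. In the conservative list 7 of the 10 regions with the highest −log10 p and 5 of the 10 distal regions with the highest signal value aligned over at least 50% of their length, among them those nearest to Galc and G6pd2, against 13 of all 17129 regions (0.0759%). Misplaced mitochondrial reads are therefore a candidate explanation for these 7 and 5 regions, while the regions nearest to Pak3, Frmd4a, Hic2 and Myl12b had no alignment. No biological explanation was tested.

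CpG content of the promoters was weighed for the gene lists. Against random lists matched on CpG content 6 of the 10 lower lists stayed lower (epicardium, neurons, germ line, pluripotency, Hox genes and olfactory receptors) and 3 of the 5 higher lists stayed higher (sarcomere, fatty acid and energy metabolism, housekeeping). Matching in deciles of CpG content around the most upstream TSS thus did not account for the calls of these lists. CpG content at other TSSs and differences inside a decile were not matched. CpG content stays fully open for the other 4 and 2 lists, among them the cardiac transcription factors and the leukocyte genes. For the leukocyte genes the matched range began at 0, so the matching could not have given a lower call. No biological explanation was tested.

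Regions of 1 replicate only were weighed against low signal near the authors' threshold and against cells of another tissue in 1 of the dissections. In both replicates at least 94.3% of them lay in the lower 50% of their own list by signal value, which low signal near the threshold needs. The share nearest to a gene of another tissue was 4.98 times that of shared regions in replicate 2, from 3 of 299 regions, and 0 in replicate 1, from 0 of 150. Overlapping intervals had been named beforehand as speaking against other tissue, but that bound was wrong, since these counts still allow ratios up to 22.3 and 25, so other tissue cannot be told apart from none. No biological explanation was tested.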

How the results depend on the processing

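The alternatives that left out regions aligned to the mitochondrial genome, or promoter regions shared with another gene, were added after seeing the data; all others were planned. No paired analysis was possible because the series has 1 group. Depth is unknown and can limit which weak regions pass the threshold in each replicate, which was not tested. Values per list depend on list length. Where a list was shortened or lengthened, or a window changed, the counts follow from that construction; for every other change below the cause was not tested. Of the single lists, motifs and regions, 1198 comparisons kept their call, 57 gained one, 69 lost one, 14 reversed and 1 moved. Of the summary counts and shares, such as regions per list, replicate overlap, annotation shares and numbers of lists standing apart, 53 stayed the same. The other 65 moved beyond the bound set for them.

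Without merging, the conservative list and the lists of replicates 1 and 2 held 35968, 23135 and 26291 peaks. Of replicate 1's regions (84.6%), 79.1% were shared by reciprocal overlap of 50%, 76.9% by summits within 100 bp, 71.4% between pseudoreplicated lists and 85.8% between the 2 replicates' lists when each was cut to its upper 50% by signal value; of replicate 2's (78.6%), 74.1%, 72.0%, 65.8% and 80.2%. Regions absent from the other replicate's IDR thresholded list numbered 1837 in replicate 1 and 2726 in replicate 2, against 150 and 299.

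In the second IDR thresholded list promoters held 59.3% and coding exons 0.659% of regions. Among replicated peaks promoters held 32.7%, UTRs 1.48%, coding exons 1.73%, introns 32.5% and intergenic sequence 31.6%. In the upper 50% by signal value these were 80.0%, 0.339%, 0.222%, 7.37% and 12%. Without replicate 1 or without replicate 2 they ranged from 70.6 to 70.7%, 0.588 to 0.692%, 0.420 to 0.440%, 12 to 12.5% and 15.7 to 16.3%. With a 500 bp promoter window they were 56.8%, 1.19%, 0.870%, 19.3% and 21.9%, and with 2000 bp 61.8%, 0.823%, 0.572%, 16.7% and 20.1%.

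For promoters, 5 lists stood higher; this became 6 in the second IDR thresholded list and with shared promoter regions left out, with conduction genes added each time, 8 among replicated peaks, 3 in the upper 50% by signal value and 3 with random lists matched on CpG content. The endothelial list turned to higher than random lists among replicated peaks (90%), and the sarcomere list turned to the lower side of the random median, still inside the range, in the upper 50% (25%). For distal regions, 1 list stood lower; this became 2 in the second IDR thresholded list, 2 among replicated peaks, 2 in the upper 50%, 2 to 2 without replicate 1 or without replicate 2, and 2 within 100000 bp. Higher distal lists fell from 5 to 3 in the upper 50% and rose to 6 in the second IDR thresholded list, among replicated peaks, without replicate 2 and within 100000 bp, with housekeeping genes added each time, and within 20000 bp, with valve genes added. With random lists matched on gene length all 21 distal calls were kept.

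Of the 10 highest clusters, 4 stayed among replicated peaks, 1 in the upper 50%, 3 to 4 without replicate 1 or without replicate 2, 0 with a gap of 5000 bp and 4 when ranked by number of regions.

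Against the dinucleotide-shuffled background 1 motif in place of 4 was lower at distal regions, and at promoters 15 in place of 9 were higher and 3 in place of 12 lower. The shorter motif window left 2 lower at distal regions. The distal HAND E-box ratio turned to 1.03 among replicated peaks. Shuffling turned the distal ratios of FOX to 2.76 and RUNX to 1.55, and the promoter ratios of GATA to 1.12, TEAD to 1.35, CArG box to 2.69, muscle E-box to 0.980, ESRR to 3, AP-1 to 1.5, SOX to 1.12, FOX to 2.76 and RUNX to 1.41.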

Other observations

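The comparison of the X chromosome with the autosomes and the count of motifs near cardiomyocyte genes were tests chosen after other results had been seen.

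Promoters on the X chromosome were accessible less often than those on autosomes. With olfactory receptors left out, 311 of 941 X-linked genes had a promoter region in the conservative list (exact 95% interval 30 to 36.2%), against 10440 of 19570 autosomal genes (53.3%). The shares were 23.8% against 44.8% in replicate 1 and 30% against 47.8% in replicate 2. Only 1 of the 1133 olfactory receptors had a promoter region, so leaving them out raises the share of the chromosomes that hold them. How much this changed the gap was not tested. The genes were not matched on CpG content, hearts of both sexes were pooled, and the cause was not tested.

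Skeletal muscle genes with distal regions included Tnnt3, which had 7 within 50000 bp in the conservative list, 1 in replicate 1 and 2 in replicate 2, and no promoter region. Among regions of replicate 1 only, the strongest were nearest to Gm17387 (11.4) and Mylk3 (10.2), and among regions of replicate 2 only those at Tmem29 (10.3) and Adat1 (10.1). These genes were chosen after their values were seen.

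It was hypothesised that sequence motifs of MEF2, TBX, NKX2, GATA and TEAD factors are more frequent at distal regions within 50000 bp of cardiomyocyte genes than at other distal regions. Of the 5 motifs 1, TEAD, had an interval above 1, with matches in 15.2% of 105 regions against 8.15% of 6642 (ratio 1.87, 1.18 to 2.96). The ratios of MEF2 (1.92, 0.871 to 4.22), TBX (1.54, 0.214 to 11.1), GATA (1.38, 0.923 to 2.05) and NKX2 (0.954, 0.527 to 1.73) had intervals that included 1. With 105 regions the counts were too few to decide, and the hypothesis stays open. MEIS, not among the 5, had a ratio of 1.48 (1.04 to 2.11).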
